A study of Phalacrocorax auritus with 32 samples.

How the data were processed

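Gene expression was measured in 32 samples of total RNA from embryos of the double-crested cormorant, a fish-eating waterbird, on 1-colour Agilent arrays with Cy3 label. Per the labels' protocols, eggs were incubated artificially at 38 degrees C and 57% humidity with no treatment, and RNA was extracted with a column kit. The samples were grouped by the tissue and incubation day in the labels, which gave 7 groups. The series text states 3 to 5 samples per day, while the labels list 6 for whole embryo day 8 and 6 for liver day 12, and all labelled samples were used. The labels do not say that the replicates came from separate eggs, so p-values measure the spread between these samples, part of which may be technical.

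Per the file headers, the authors scanned the arrays and extracted spot intensity values with Agilent Feature Extraction 12.0.3.1, which subtracted background and corrected spatial trends within each array. These intensity values were not normalised between arrays. The deposited value table of the series holds log2 values whose sorted columns differ by at most 0.281, as after quantile normalisation, with a floor of 3.60. Each of its 32 columns correlated best with the scanner file of the same sample, with a median Spearman rho of 0.967. Its scale and its lack of gene centring were read from the values, and the source of its floor is not given in the sources used here. The submitters' processing notes name limma without a version. The arrays came on 4 slides of 8, each slide held several groups, and all were scanned on 1 day, so slide was the batch that could be tested.

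Each array held 15208 spots other than controls, for 14383 distinct probes of 60 bases, and 825 probes had 2 spots. The 536 control spots and between 0 and 53 outlier spots per array were left out, and no spot was saturated. Every accession had 1 probe, but whether several accessions belonged to 1 gene could not be told without gene names. The rule for choosing among several probes of a gene could therefore not be applied. The files do not pair the probe IDs with gene names, and no reference table was used. Gene lists and anchor genes fixed before the data were examined could therefore not be matched, so none of those lists was tested, and the rule for named genes was applied to probe IDs. It took probes with an adjusted p under 0.05 and no overlap between the groups, ranked by log2 change. Of these the 2 largest rises and 2 largest falls are given, not the 10 of each first set, because only probe IDs could be printed. No genome was used, so positions in a genome are not given.

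Levels were log2 of the processed intensity minus the array's 75th percentile, averaged over the spots of a probe. A probe was tested if it was well above background on at least 3 arrays of at least 1 group, which kept 11048 probes and left out 3335. The 75th percentile of intensity ran from 54.2 to 305 across arrays, and the share of probes well above background from 51.6% to 76.0%. The number of arrays and the signal over background limit the precision. A probe not well above background on every array of a group has only a bound there. Its change is given as at least N-fold, the mean of the brighter group against, on each dim array, the higher of the lowest detected signal and the probe's own. Where only some arrays of the lower group were dim, the change is given as estimated, and its size rests in part on signals near background.

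One model with a coefficient for each of the 7 groups was fitted to all arrays with limma 3.58.1 in R 4.3.3, and 7 pairs of groups were compared with its two-sided moderated test. A moderated F test from the same fit covered the 5 liver days. Adjusted p-values are Benjamini-Hochberg values over the tested probes, with a threshold of 0.05. The fit was tested on simulated data, drawn anew for each comparison, with 200 changed probes among the 11048. The noise was independent between probes and arrays, with no slide or brightness effect. Real arrays share such deviations, so false calls can be more and recovery can differ there. For whole embryo day 8 against day 5 it recovered 87.9% of 4-fold changes, 28.4% of 2-fold changes and 7.46% of 1.5-fold changes, with 5 false calls. For liver day 16 against liver day 14, the comparison with the fewest arrays, it recovered 77.3%, 13.4% and 2.98%, with 0 false calls.

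After the data were examined, 2 sets of probes were defined from liver day 12 against whole embryo day 8 with an adjusted p under 0.05 and at least a 4-fold change. They are called liver-enriched, with 820 probes, and embryo-enriched, with 1081. They were tested with limma's cameraPR, at a preset correlation of 0.01 and at an estimated one, only in comparisons that share no array with their definition. The brightest liver-enriched probes were the 104 at least 16-fold higher in liver day 12 and at least 7 log2 units above the lowest percentile of detected signals, averaged over arrays. A position for each liver array was computed by projecting its levels on the line from the day 12 mean to the day 24 mean, with the array itself left out of both means. Positions were compared with exact permutation tests.

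Same-numbered arrays deviated together, with every correlation over 0.1, only in liver day 14 against liver day 12, where the 3 correlations of deviations ran from 0.198 to 0.441. The replicate numbers come from the sample titles. Alternatives set before the data were examined were normexp with an offset of 50 and quantile normalisation, quantile normalisation of the processed signal, the array median, the authors' value table, 2 other filters on dim probes, slide as a fixed or random block, the replicate number as a block, fits to the compared groups alone, array weights, trended and robust eBayes, an added 2-fold threshold, and leaving out each array. Array brightness as a covariate and the removal of arrays in doubt were added after the data were examined, as was a check that called probes without 1 slide and read their sign on it. Other splits of the arrays were limited to 100 per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.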

Results

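Transcript levels of the double-crested cormorant were profiled through incubation, in whole embryos on days 5 and 8 and in embryonic liver on days 12, 14, 16, 20 and 24. Whole embryo day 5 had 4 arrays and day 8 had 6. Liver had 6 arrays on day 12, 3 on day 14, 3 on day 16, 5 on day 20 and 5 on day 24. The series set each sampling day against the one before and the one after, to follow expression over development. Of 11048 probes tested, most differences lay between tissues. Group means of whole embryo day 8 and liver day 12 had a Spearman rho of 0.801 across probes, against 0.972 between the embryo days and 0.987 between liver days 12 and 14. Probes are not independent replicates. The first principal component held 63.0% of the variance and parted embryo from liver, and the second, with 8.07%, ran along the liver days. On average 73.2% ± 2.09 (SD, n = 4) of probes were well above background in whole embryo day 5, and 60.7% ± 2.16 (SD, n = 6) in liver day 12.

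**Figure D1:**
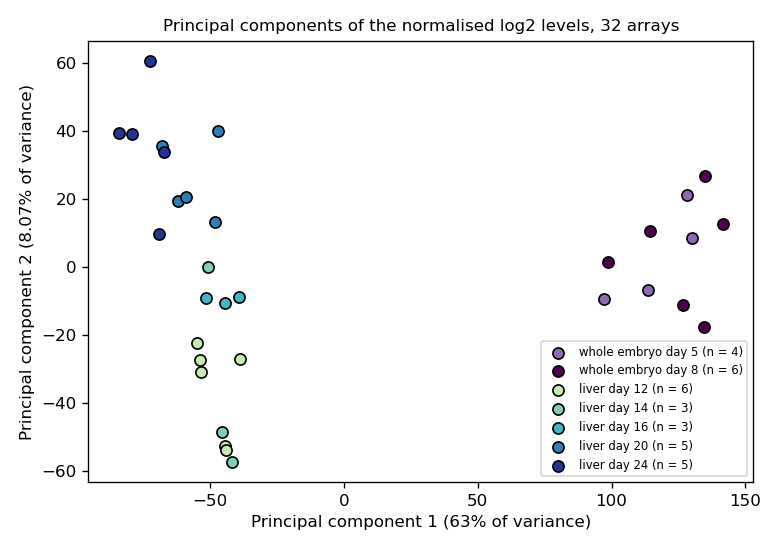
Scores of the 32 arrays on the first and second principal components of the normalised log2 levels, 1 point per array, coloured by group. The first component, with 63.0% of the variance, separates the 10 embryo arrays from the 22 liver arrays, and the second, with 8.07%, spreads the liver arrays.

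Between whole embryo day 5 and day 8, 473 probes changed, of which 270 rose and 203 fell. At least 4-fold changes were seen for 68 rises and 65 falls. Probe GT_XM_009514621.1_11987 was not well above background on the day 5 arrays and rose at least 24.2-fold (limma adjusted p = 1.74e-09, n = 6 and 4). GT_XM_009506448.1_5910, also not well above background on day 5, rose at least 12.2-fold (limma adjusted p = 4.03e-09). GT_XM_009512215.1_1091 fell by 5.54 ± 0.49 (SE) on the log2 scale (limma adjusted p = 1.52e-08), from 0.48 ± 1.11 (SD, n = 4) to -5.05 ± 1.05 (SD, n = 6), where 2 of 6 arrays were well above background. GT_XM_009505490.1_13624 was at least 14.8-fold lower on day 8, where it was not well above background (limma adjusted p = 7.82e-07). With normexp, which adds an offset of 50 to each signal, these 4 log2 changes shrank to 1.03, 0.55, -1.88 and -1.08. Of the 11048 probes, 752 had groups that did not overlap, where chance gives 105. The embryo-enriched set held 119 probes that rose and 9 that fell, and the liver-enriched set 20 that rose and 54 that fell. Both sets were defined in part on the day 8 arrays, so these counts are not independent evidence of a direction. The liver-enriched transcripts also differed among embryo arrays of 1 group. Over the 104 brightest of them the median level, as a percent of liver day 12, was 5.05% in day 5 replicate 3 and 4.81% in day 8 replicate 6, and 0.157% to 2.68% in the other 8 embryo arrays. Without day 5 replicates 2 and 3 and day 8 replicates 3 and 6, a choice made after seeing the data, 68 probes were called, and the count was 154 without day 5 replicate 3, 259 without day 5 replicate 2 and 296 without day 8 replicate 4. It was 282 in a fit to these groups alone, 716 with array weights and 822 in the authors' value table. Scaling to the array median gave 188 rises and 251 falls, a share of rises of 42.8% against 57.1%, and moved the median change of all probes from 0.04 to -0.06 on the log2 scale.

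From whole embryo day 8 to liver day 12 the profile changed across most of the array, with 6991 of the 11048 probes called. There were 2587 probes higher in liver and 4404 lower, and 820 and 1081 of them differed at least 4-fold. Probe GT_XM_009510740.1_2315 was 10.45 ± 0.91 (SE) higher in liver on the log2 scale (limma adjusted p = 7.85e-11), with 6.83 ± 0.35 (SD, n = 6) in liver and -3.62 ± 2.91 (SD, n = 6) in embryo. GT_XM_009508477.1_4199 was 10.29 ± 0.87 (SE) higher (limma adjusted p = 4.86e-11). Of the 6 embryo arrays, 3 measured the first of these well above background and 2 the second. GT_XM_009511945.1_1314 fell by 9.43 ± 0.43 (SE) on the log2 scale (limma adjusted p = 2.26e-16) and was well above background on 1 of 6 liver arrays. The size of this fall is therefore set mostly by signals near background. GT_XM_009510374.1_2622 fell by 8.27 ± 0.47 (SE) on the same scale (limma adjusted p = 1.93e-14) and was measured on all 12 arrays. With normexp the first 3 of these changes were 6.53, 6.14 and -5.75. A further pattern was of presence: 446 probes were well above background on all 6 embryo day 8 arrays and on none of the 6 liver day 12 arrays, and 112 the other way. Over all probes on the array, 68.8% were well above background in whole embryo day 8 and 60.7% in liver day 12 on average. Tissue and age changed together in this step and could not be separated. The median change of all probes was -0.28 on the log2 scale, and 0.03 when arrays were scaled to their median, which gave 3433 higher and 3021 lower.

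**Figure D2:**
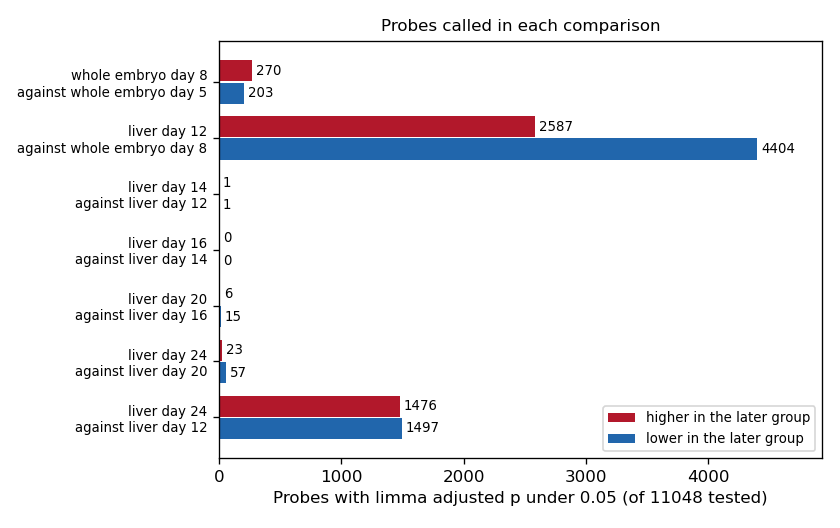
Number of probes with a limma adjusted p under 0.05 in each of the 7 comparisons, with bars for probes higher and lower in the later group, of 11048 tested. The step from whole embryo day 8 to liver day 12 has 2587 rises and 4404 falls, and the 4 steps between neighbouring liver days have at most 57 in a direction.

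From liver day 12 to day 14, 2 probes were called, with 1015 at an unadjusted p under 0.05. With 3 arrays against 6, simulated 4-fold changes were recovered in 83.3% of cases and 2-fold changes in 41.8%. GT_XM_009504342.1_7694 rose by 3.33 ± 0.60 (SE) on the log2 scale (limma adjusted p = 0.033), from -2.57 ± 0.81 (SD, n = 6) to 0.76 ± 0.76 (SD, n = 3). GT_XM_009500241.1_14070 was at least 5.22-fold lower on day 14 (limma adjusted p = 0.0105), where it was not well above background. The rise lost its call in 11 of 23 other fits, counting those without 1 array, and the fall in 4 of 23, and with normexp they were 1.57 and -0.40. On the 3 slides that held both days, from the same arrays as the call, the rise was 2.58, 2.14 and 5.35 and the fall -2.86, -2.45 and -3.16. Of 7 probes called without slide 2, 5 had the same sign on it, and the 1 called without slide 3 did not. Same-numbered arrays of these days deviated together, but 2 of the 3 pairs shared a slide, and the numbers come only from the sample titles. Whether the samples were paired therefore cannot be told. The fit with the replicate number as a block called 0 probes, as did slide as a fixed block and the fit without day 14 replicate 1. The count was 13 without day 14 replicate 3, 12 without day 12 replicate 2, 11 without day 12 replicate 1, and 1 without day 12 replicate 4, 5 or 6. It was 1 in a fit to these groups alone, 4 with slide as a random block, 5 with the array median, 6 with array weights, 7 with normexp, 8 with quantile normalisation, and 11 in the authors' table and without day 14 replicate 3 and day 24 replicate 3.

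From liver day 14 to day 16, limma called 0 probes, with 707 at an unadjusted p under 0.05. Spearman rho between arrays, across probes, ran from 0.944 to 0.963 among the day 14 arrays and from 0.966 to 0.968 among the day 16 arrays. The liver-enriched probes had a median log2 difference of -0.08 against 0.09 for the other probes (cameraPR adjusted p = 0.000552), a call kept with slide as a block (adjusted p = 0.00083) and lost with an estimated correlation (adjusted p = 0.501). The set's median was -0.41 on slide 1, where all probes had 0.01, and 0.09 on slide 2, where all probes had 0.24. The embryo-enriched probes had a median of 0.14 against 0.08 (cameraPR adjusted p = 0.915). With 3 arrays against 3, simulated 4-fold changes were recovered in 77.3% of cases and 2-fold changes in 13.4%. Without day 14 replicate 3 the fit called 8 probes, without day 24 replicate 3 as well 12, with array weights 3 and with slide as a fixed block 1.

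From liver day 16 to day 20, 21 probes changed, of which 6 rose and 15 fell. GT_XM_009502779.1_9019 rose by 2.29 ± 0.49 (SE) on the log2 scale (limma adjusted p = 0.0412), and was well above background on 1 of 3 arrays on day 16 and 4 of 5 on day 20. GT_XM_009511595.1_1606 rose by 1.76 ± 0.37 (SE) on that scale (limma adjusted p = 0.0397), measured on 1 of 3 and 3 of 5. GT_XM_009514012.1_12508 fell by 3.28 ± 0.50 (SE) (limma adjusted p = 0.00368), from -1.79 ± 0.34 (SD, n = 3) to -5.07 ± 0.96 (SD, n = 5), and GT_XM_009508804.1_3925 fell by 3.02 ± 0.48 (SE) (limma adjusted p = 0.00368). Both were well above background on 1 of 5 arrays on day 20, so the size of these falls is set mostly by signals near background. The 2 rises lost their call in 10 and 12 of 22 other fits and the 2 falls in 2 of 22 each. With normexp the 4 changes were 0.57, 0.35, -0.66 and -0.54. Without slide 2 the fit called 0 probes, and without slide 1 it called 1, with the same sign on slide 1. Of 16 called without slide 4, 12 had the same sign on it, or 75%, against 60.7% of all probes. Among the 1081 embryo-enriched probes, 9 fell and 0 rose, and their median log2 change was -0.17 (cameraPR adjusted p = 4.16e-05; adjusted p = 0.344 with an estimated correlation; adjusted p = 0.0048 with slide as a block). On the 3 slides with both days that median was -0.01, -0.14 and -0.37, against 0.04, -0.05 and -0.01 for all probes, and it was 0.00 in the authors' value table. On average 29.1% of embryo-enriched probes were well above background on day 16 and 25.2% on day 20, so most lay near the floor. The mean 75th percentile of intensity was 89.4 on day 16 and 128 on day 20, and the set was not tested with brightness as a covariate. Among the 820 liver-enriched probes, 1 rose and 0 fell (cameraPR adjusted p = 0.915). The count of 21 was 0 with normexp and in a fit to these groups alone, 4 with the replicate block, 6 with slide as a fixed block and 8 with no filter on dim probes, and the array median gave 6 rises and 7 falls. It was 35 with brightness as a covariate, 52 without day 14 replicate 3 and day 24 replicate 3, and 92 with array weights. It was 7, 11 and 11 without day 16 replicates 1, 2 and 3, and 12, 9, 4 and 41 without day 20 replicates 2, 3, 4 and 5.

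From liver day 20 to day 24, 80 probes changed, with 23 rises and 57 falls, and falls reached 4-fold in 32 and rises in 8. GT_XM_009502106.1_9589 fell by 6.87 ± 0.67 (SE) on the log2 scale (limma adjusted p = 6.29e-07), from 2.90 ± 0.41 (SD, n = 5) to -3.97 ± 1.42 (SD, n = 5), and 3 of 5 arrays measured it above background on day 24. GT_XM_009509873.1_3033 was at least 19.1-fold lower on day 24, where it was not well above background (limma adjusted p = 0.00175), a call lost in 1 of 24 other fits. GT_XM_009511520.1_1670, well above background on 1 of 5 arrays on day 20 and on all 5 on day 24, rose by 2.08 ± 0.51 (SE) on the log2 scale (limma adjusted p = 0.0499), a call lost in 13 of 24 other fits. GT_XM_009505308.1_6872, not well above background on day 20 and above it on 2 of 5 arrays on day 24, rose at least 3.14-fold (limma adjusted p = 0.0394), a call lost in 10 of 23. Its day 24 mean, and with it this bound, rested on replicate 2, at -0.03 where the other 4 arrays lay at -4.77 to -3.32. Without that array the log2 change was 1.45 in place of 2.25, so the bound does not hold without it. With normexp the falls were -3.35 and -1.13 and the rises 0.43 and 0.35. Without slides 1, 2, 3 and 4 in turn the fit called 29, 22, 206 and 20 probes. Of these 89.7%, 100%, 74.5% and 100% had the same sign on the slide left out. Among all probes the shares were 60.8%, 63.0%, 54.2% and 60.7%. Of the embryo-enriched probes, 38 fell and 1 rose, with a median log2 change of -0.42 against -0.04 for the other probes (cameraPR adjusted p = 1.71e-10; adjusted p = 0.197 with an estimated correlation; adjusted p = 5.92e-11 with slide as a block). Of the liver-enriched probes, 9 rose and 2 fell, with a median of 0.17 against -0.07 (cameraPR adjusted p = 5.7e-07; adjusted p = 0.344 with an estimated correlation; adjusted p = 7.44e-07 with slide as a block). Across the 4 slides the embryo-enriched median was -0.06, -0.35, -0.44 and -0.43, and the liver-enriched median 0.27, 0.21, -0.03 and 0.31, against -0.04, -0.18, -0.06 and -0.02 for all probes. On day 24 on average 25.9% ± 13.4 (SD, n = 5) of embryo-enriched probes were well above background, so most of them lay near the floor of the measurement, and their median change was 0.00 in the authors' value table. Among the scalings compared, falls outnumbered rises except with normexp, which gave 56 rises and 23 falls, and in the authors' table, with 37 and 26. The count of 80 was 22 in a fit to these groups alone, 211 with array weights and 321 without day 14 replicate 3 and day 24 replicate 3. It was 301 without day 24 replicate 3, and 52, 44, 32 and 50 without day 24 replicates 1, 2, 4 and 5, and 34 and 44 without day 20 replicates 2 and 5.

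**Figure D3:**
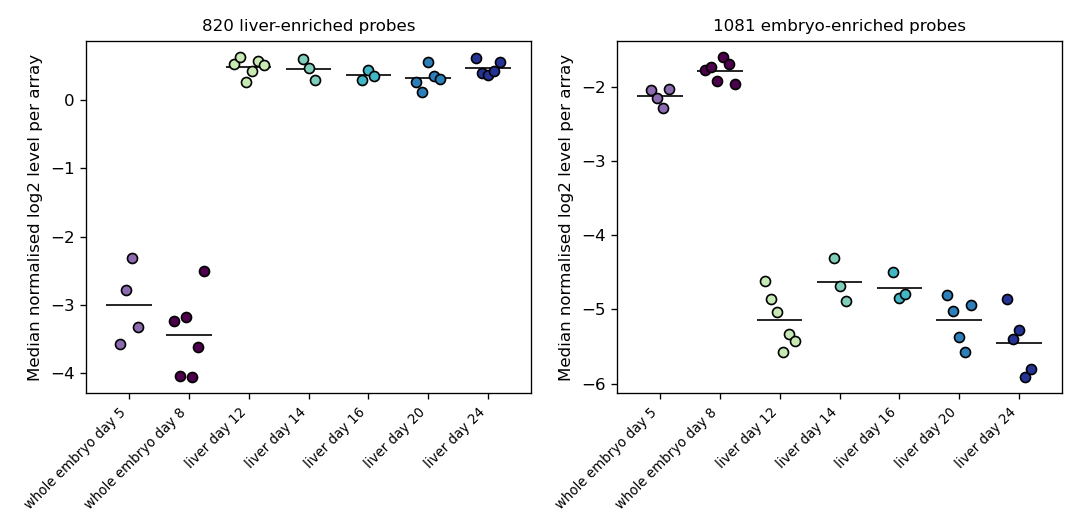
Median normalised log2 level per array of the 820 liver-enriched probes (left) and the 1081 embryo-enriched probes (right), 1 point per array in 7 groups, with a line at the group mean. Liver-enriched means lie between 0.32 and 0.49 on the 5 liver days, and embryo-enriched means between -4.63 on day 14 and -5.45 on day 24, where most of these probes are not well above background.

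Over the whole liver series the profile moved far. Between day 12 and day 24, 2973 probes changed, with 1476 rises and 1497 falls, of which 137 and 195 reached 4-fold. GT_XM_009506376.1_5971 was not well above background on the 6 day 12 arrays and rose at least 248-fold (limma adjusted p = 2.65e-08). GT_XM_009505966.1_6317, also not well above background on day 12, rose at least 38.4-fold (limma adjusted p = 8.58e-06). GT_XM_009510490.1_2526, well above background on all 11 arrays, fell by 6.49 ± 0.66 (SE) on the log2 scale (limma adjusted p = 9.33e-08), from 8.28 ± 0.70 (SD, n = 6) to 1.79 ± 1.41 (SD, n = 5). GT_XM_009514012.1_12508, which fell between days 16 and 20, fell by 5.39 ± 0.41 (SE) from day 12 to day 24 (limma adjusted p = 5.94e-10), and was well above background on 6 of 6 arrays on day 12 and 1 of 5 on day 24. With normexp the 2 rises were 3.89 and 1.80 on the log2 scale, and this fall was -1.45. Of the probes called without 1 slide, between 82.3% and 95.4% had the same sign on that slide, against 65.8% to 73.0% of all probes. Groups did not overlap for 1357 of the 11048 probes, where chance gives 47.8.

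The F test across the 5 liver days called 2874 probes, and 1862 of these had day means at least 2-fold apart. The highest mean fell on day 24 for 807 probes, on day 12 for 646, on day 20 for 547, on day 14 for 542 and on day 16 for 332. The means rose at every step for 283 probes and fell at every step for 248. On the line from the day 12 to the day 24 mean, the mean position was 0.16 ± 0.23 (SD, n = 3) on day 14, 0.34 ± 0.02 (SD, n = 3) on day 16 and 0.70 ± 0.12 (SD, n = 5) on day 20. Day 12 arrays themselves averaged 0.09 ± 0.06 (SD, n = 6), from 0.036 to 0.173. Day 24 arrays averaged 0.89 ± 0.25 (SD, n = 5). The day 14 mean rested on replicate 3, at 0.406, as replicates 1 and 2 lay at 0.115 and -0.038. Day 20 was above day 16 by 0.355 and above day 14 by 0.537, each with a two-sided exact permutation p = 0.0179, the smallest the 56 splits allow, and an adjusted p = 0.0268 over the 3 pairs. Day 16 was above day 14 by 0.182 (exact permutation p = 0.4, with a smallest possible p of 0.1). On slide 1 the positions for days 14, 16 and 20 were 0.115, 0.338 and 0.584, and on slide 2 they were -0.038, 0.325 and 0.807. Slide 3, which held no day 16 array, had 0.406 on day 14 and 0.647 and 0.838 on day 20, and slide 4, with no day 14 array, had 0.366 on day 16 and 0.616 on day 20.

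**Figure D4:**
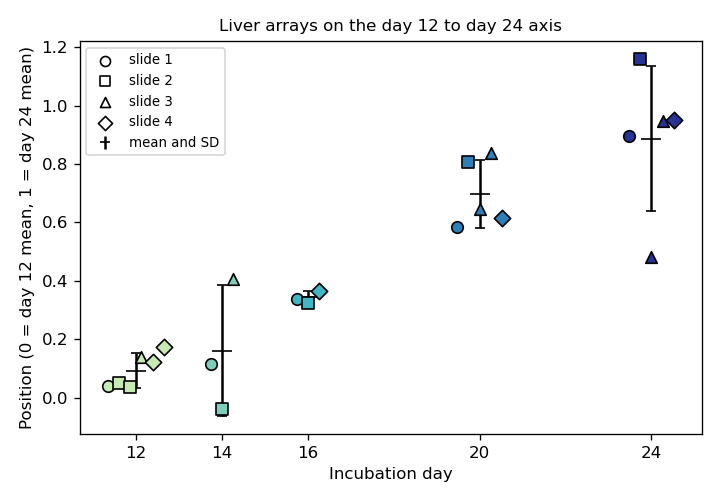
Position of the 22 liver arrays on the line from the day 12 mean (0) to the day 24 mean (1) against incubation day, 1 point per array, with the slide as its shape and bars for the mean and SD of each day. Day 14 replicate 3 lies at 0.406 and day 24 replicate 3 at 0.480, away from the other arrays of their days.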

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

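The tests on liver-enriched probes in embryo arrays, and the test of exchanged labels, were chosen after the result was seen. The test of a mixture replaced a first one on probes peaking on days 16 and 20, which had only 2 and 3 probes and could not decide. In 61 groups of 4 to 10 values, no highest or lowest array stood apart by Dixon's test, where chance alone gives about 3.05 such cases. Groups of 3 arrays, as on liver days 14 and 16, were below this size, so day 14 replicate 3 was not tested against its day. The test also has little power in groups this small, so it does not show that no array was aberrant.

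Liver day 14 replicate 3 lay at 0.406 and liver day 24 replicate 3 at 0.480 on the line from day 12 to day 24, while the other day 14 arrays lay at 0.115 and -0.038 and the other day 24 arrays at 0.898 to 1.16. Array brightness was argued against, since after regression on it the arrays lay at 0.412 and 0.49, still outside the other arrays of their days by more than the largest SD of a liver day, 0.246. An exchange of the 2 labels was argued against by the gap of 0.493 between day 14 replicate 3 and the lowest other day 24 array. A mixture of day 14 and day 24 RNA was argued against because probes that fell by day 24 and probes that rose gave unlike shares of day 24 RNA, 0.751 and 0.0719 for day 14 replicate 3 (difference 0.679) and 0.809 and 0.09 for day 24 replicate 3 (difference 0.719). Both arrays were on slide 3, and after regression on slide they lay at 0.406 and 0.491. The other liver arrays of slide 3 lay at 0.138 on day 12, 0.647 and 0.838 on day 20 and 0.947 on day 24. Whole embryo day 5 replicate 3, described below, was also on slide 3, and a cause shared by these arrays was not tested. A wrong label on a single array, and embryos that were ahead of or behind their incubation day, stay open and were not tested.

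Liver-enriched probes stood at different levels in whole-embryo arrays of 1 group. In day 8 replicate 6 the distance of the 104 brightest from liver day 12 had an SD over probes of 0.811 on the log2 scale. It ranged from -5.5 to -3.37 between the 10th and 90th percentile. In the other embryo arrays the SD was 1.41 to 2.91. A uniform share of liver RNA, from liver within the embryo or RNA carried over, could give the lower spread. The probes were chosen in part on the level of this array, so the result is not independent evidence for such a share. In day 5 replicate 3 the SD was 2.73, with a range from -8.09 to -1.88 between the 10th and 90th percentile, which argues against a uniform share of day 12 liver RNA there. Embryonic tissues that share transcripts with liver, in amounts that differ between embryos or dissections, stay open for that array and were not tested.

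Levels of 1640 probes followed the brightness of the array within groups (limma adjusted p under 0.05), 407 rising and 1233 falling. The slope on brightness had a Spearman rho of -0.449 with the GC content of the probe, across probes, which are not independent, as an effect of GC content on labelling or hybridisation could give. With slide as a block 7.07% of these probes were called, as an effect of slide could give. A block also takes up the brightness that differs between slides, and slopes were not compared, so the lost calls alone do not decide this. The share of such probes in the dimmest tercile of probes was 1.84 times that in the brightest, 21.5% against 11.7%. Levels were taken relative to each array's own intensity, so a probe near background can read lower on a brighter array. The 1233 falls against 407 rises, and the larger share of dim probes, could come from such an effect of low signal. How many of the 1640 probes it accounts for was not tested and stays undecided. No biological explanation was tested.

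Other splits of the same arrays were counted for each result. Chance was excluded for whole embryo day 8 against day 5, where 1 of 100 splits, the real one with 473 probes, gave as many and the highest other gave 135. That split set day 8 replicates 3 and 6 with the day 5 arrays. Chance was excluded for liver day 12 against whole embryo day 8 (1 of 100, real 6991, highest other 4766), liver day 24 against day 12 (1 of 100, real 2973, highest other 1881) and the F test over the 5 liver days (1 of 100, real 2874, highest other 298). For liver day 20 against day 16, only the real split of 56 gave as many (real 21, highest other 9). That count was 0 with normexp and in a fit to these groups alone, so chance was not firmly excluded there. For liver day 24 against day 20, 4 of 100 splits, the real one included, gave at least the real 80, a share under 0.05. The shares were not adjusted over the results, and the highest other split gave 263, so chance was not firmly excluded. That split exchanged day 24 replicate 3 and day 20 replicate 4, so it points to a structure of the samples. For liver day 14 against day 12 chance was not excluded, since 16 of 84 splits gave 2 or more. The highest, with 428, set day 12 replicate 2 with day 14 replicates 1 and 2, arrays of slides 1 and 2. This again points to a structure of the samples. These arrays were also dim, with a 75th percentile of intensity of 72.9, 54.2 and 87.3, against 79.1 to 190 in the other arrays of these days. Slide and brightness were not told apart here. The count for the real groups was 0 with slide as a fixed block, 4 with it as a random block and 2 with brightness as a covariate. For liver day 16 against day 14 the 10 splits are too few for a share under 0.05, and all 10 gave at least the real count of 0, with 3 in the highest other.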

How the results depend on the processing

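The brightness covariate and the fits without arrays in doubt were chosen after the data were seen, the rest before. In all settings run, the counts for liver day 12 against whole embryo day 8, liver day 24 against day 12 and the F test stayed within 1.5 times, except that a 2-fold threshold gave 4433 and 1443 for the first 2. Causes were not tested, except that fewer arrays or a stricter threshold follow from the setting itself. For whole embryo day 8 against day 5 (473), the authors' table gave 822, array weights 716, the compared groups alone 282, and the 4 embryo arrays left out 68. For liver day 14 against day 12 (2), normexp gave 7, quantile 8, the array median 5, the authors' values 11, slide as a fixed block 0, as a random block 4, the replicate block 0, the compared groups alone 1, array weights 6 and the 2 liver arrays left out 11. For day 16 against 14 (0), slide as a fixed block gave 1, array weights 3 and the 2 arrays left out 12. For day 20 against 16 (21), normexp gave 0, the array median 13, no filter 8, slide as a fixed block 6, the replicate block 4, the compared groups alone 0, array weights 92, brightness 35 and the 2 arrays left out 52. For day 24 against 20 (80), the compared groups alone gave 22, array weights 211 and the 2 arrays left out 321, of which 78 were among the 80. With 1 array left out at a time, counts ran from 154 to 547 (embryo day 8 against 5), 6655 to 6871 (liver day 12 against embryo day 8), 0 to 13 (day 14 against 12), 0 to 8 (16 against 14), 4 to 41 (20 against 16), 32 to 301 (24 against 20), 2236 to 3253 (24 against 12) and 2449 to 3584 (F test).

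Named probes were chosen with no overlap between the groups, so leaving out arrays or fitting the compared groups alone could not reverse a sign. The 22 changes of named probes kept their sign in each setting, but not their size. With normexp 20 of them shrank by over 1.5 times, and 12 in the authors' table. Among fits without 1 array this was so only for 1 change, without liver day 24 replicate 2. The offset of 50 in normexp and the floor in the authors' values compress dim signals. The changes passed the threshold in 280 of 311 fits under other settings and in 188 of 222 with 1 array left out. Those that did not were in the steps from day 12 to 14, 16 to 20 and 20 to 24, where each named rise lost its call in between 10 and 13 fits. The array median in place of the 75th percentile moved the median change of all probes from 0.02 to -0.14 (log2) for liver day 14 against day 12. The 4 set shifts that passed with the preset correlation did not pass with an estimated one, and passed with the other scalings, the slide block and without the 2 liver arrays. Beyond the calls given here, the replicate block moved no count by more than 1.5 times. Outside liver day 14 against day 12 the numbers were not taken as pairs, as at least 1 correlation of deviations per comparison was under 0.1, although others reached 0.388 and same-numbered arrays often shared a slide, as all 5 pairs of liver day 24 against day 20 did. Averaging probes of a gene, and the fixed gene lists, with fry, were not run for want of names. Low signal over background limits probes on dim arrays, which had 51.6% of probes well above background at the least.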

Other observations

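Probes called in the late steps of liver were set against those called in the step from embryo to liver, in comparisons that share no array. The counts stand beside those of independent lists, without a test, since probes are not independent. All calls also came from 1 fit with a shared estimate of each probe's spread, which can make lists overlap more than independent ones. Of the 57 probes that fell from liver day 20 to day 24, 46 had been lower in liver day 12 than in whole embryo day 8, where independent lists would share 22.7. Of the 23 that rose, 12 had been higher in liver day 12, against 5.39. Of the 15 that fell from day 16 to day 20, 14 had been lower in liver day 12, against 5.98. Of the 6 that rose in that step 1 had been higher in liver day 12, against 1.4, and 2 lower, against 2.39, too few to tell. All 15 also fell from day 12 to day 24, against 2.03, and of the 6 that rose 4 also rose over that span, against 0.802. Tested as shifts of the embryo-enriched and liver-enriched sets, these directions were lost at an estimated correlation, with a cameraPR adjusted p = 0.197 and 0.344 from day 20 to 24 and 0.344 for the embryo-enriched set from day 16 to 20. Normexp gave 56 rises and 23 falls from day 20 to 24. The embryo-enriched median was 0.00 in the authors' table in both steps, where values at the floor of that table show no change. In that table the set still shifted down in both steps at the preset correlation (cameraPR adjusted p = 0.0324 for each).

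Changes between the embryo days overlapped with those from liver day 12 to day 24 by about as much as independent lists would. Of the 270 probes that rose from whole embryo day 5 to day 8, 44 rose and 31 fell from liver day 12 to day 24, against 36.1 and 36.6. Of the 203 that fell, 29 fell and 22 rose, against 27.5 and 27.1. Overlaps with the shorter steps were of 0 to 3 probes, too few to tell. Of the 270, 1 rose and 1 fell from liver day 16 to day 20, against 0.147 and 0.367, and of the 203, 2 rose and 1 fell, against 0.11 and 0.276. From day 20 to day 24, 0 and 3 of the 270 rose and fell, against 0.562 and 1.39, and 0 of the 203 changed, against 0.423 and 1.05.

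Probe sequences were translated to look for 2 protein motifs, as hypotheses written before the levels were seen. Homeodomain proteins, which pattern the embryo, could be lower in liver than in the whole embryo. The 4 tested probes with that motif had a median log2 change of -2.28 from embryo day 8 to liver day 12, against -0.28 for all probes, and 3 fell and 1 rose. Probes with the EF-hand motif of calcium-binding proteins, also 4, had a median of -3.04, and 3 fell and 0 rose. The limma cameraPR adjusted p = 0.154 for each class, over both. With so few probes neither hypothesis was decided.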
